A study of Homo sapiens with 16 samples.

How the data were processed

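RNA from 16 cultures of 2 human prostate cancer cell lines, PC3 and ARCaP(M), was measured by 3′ messenger RNA sequencing (QuantSeq, forward kit) with 50 bp single reads spread over 2 lanes of a single run. Per the labels, each line had 4 cultures alone and 4 cultures kept for 48 to 72 h in Transwell inserts above adipocytes differentiated from cells the labels call mBMSC. Growth medium went with the line, holding 10% fetal bovine serum for PC3 and 5% for ARCaP.

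The submitters' processing notes list CASAVA 1.8.2, the aligner STAR and the genome build GRCh38. The program that counted reads, the annotation it used and whether it counted by strand are not given in the sources used here. One deposited table per line holds raw whole-number counts per gene symbol, with lanes already summed to 1 column for each of its 8 libraries. Beside them the authors give a log2 fold change of co-culture over alone and a log2 mean of counts-per-million, which is equal in both tables for all 27466 entries compared (tolerance 1e-06). Per the file headers the other columns are a likelihood ratio, taken here as a test score, an unadjusted p-value and an adjusted p-value (FDR) of the authors' own comparison, whose software is not given in the sources used here. The tests reported were computed anew from the counts, and the authors' columns served only for the number of genes under an FDR of 0.05 in their tables.

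Each table had 27470 entries. Of these, 27 carried a calendar date in place of a gene symbol, a known effect of spreadsheet programs, and were left out because the symbol cannot be read back; they held 0.122 to 0.190% of the counts of a library. All 16 libraries were kept. A single entry, LOC109910383, took 7.36 to 11.1% of the counts, the 10 most abundant entries together 12.1 to 17.9%, and the entry RNR1 0.255 to 0.494%. Totals ran from 9728687 to 17808227 counts per library. Reads carry no molecular identifiers in the tables, so the limit of 3 counts given for a gene at 0 counts covers counting error only.

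Each line was fitted separately over its 8 libraries, with culture condition as the only term. Genes passing edgeR's filterByExpr were scaled by the trimmed mean of M-values (TMM) and tested with edgeR's quasi-likelihood F test (two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a fold change was taken as its size divided by the square root of F. The difference between the lines was tested by the same method over all 16 libraries as the contrast of the changes (PC3 minus ARCaP). Genes called in the same direction in both lines were counted among those tested in both and compared with chance by a one-sided Fisher exact test. Levels are counts-per-million scaled by TMM, log2 levels used a prior count of 2, and the principal components were computed from log2 levels of the tested genes of a line.

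The text works with 23 gene lists holding 425 symbols, 412 of which were found (12 through a synonym, such as RNR1 and RNR2 for the mitochondrial ribosomal RNAs) and 13 not. They cover ER chaperones with ATF6/XBP1 targets, PERK/ATF4 targets, cholesterol biosynthesis, fatty acid synthesis, lipid droplets with uptake and oxidation, glycolysis, hypoxia, NRF2, cytosolic heat shock, metallothioneins, glucocorticoid receptor targets, NF-kB, interferon, mitosis, DNA replication, p53 targets, epithelial-mesenchymal transition, lysosomes, oxidative phosphorylation, mitochondrial transcripts, and markers of adipocytes, stroma and haematopoietic cells. A list with at least 5 tested members was tested with limma's camera (inter-gene correlation 0.01, Benjamini-Hochberg over the lists), again with an estimated correlation, and with fry.

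Genes were named by a rule. Per line it takes the 10 largest rises and 10 largest falls among genes past the threshold with at least 10 CPM on average and no overlap between the groups; HSPA5, XBP1, ATF4, DDIT3, HMOX1 and PLIN2 in every case; and, of each list described, up to 4 members with the smallest p. Between the lines it takes the 10 genes called in both whose weaker change was largest and the 10 with the smallest p of the difference, with the same minimum. Of the genes this rule takes, 2 are not reported here, though they stay in all fits, lists and counts of genes. The groups, the tests, the lists and this rule were fixed before the data were examined, as were these alternatives: DESeq2, RLE size factors, no filter or a minimum of 10 CPM, the replicate number as a block, each library left out in turn, a threshold of 0.01, a minimum change of 1 log2 unit, and the set tests just named. Chosen after the data had been seen were leaving out ARCaP co-culture library 2 or PC3 co-culture library 4 from every count, scaling by library totals, and thinning all libraries to equal totals. The set tests of the difference between the lines were added after the results per line, and 6 further lists after the main results.

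Gene positions were taken from GENCODE 29 (GRCh38) and synonyms from the RefSeq annotation, which may differ from the annotation behind the tables. Annotated genes that overlap can share or lose 3′ reads. Examples among the genes named are FEN1 with FADS2, HSPE1 with HSPE1-MOB4, BUB1B with BUB1B-PAK6 and TXNRD1 with EID3 on the same strand. TOE1 overlaps genes on the opposite strand.

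The tests were tested on simulated data drawn from the real means, depths and dispersions, with 200 genes changed. For PC3, ARCaP, ARCaP without co-culture library 2 and the difference, the tests found 22, 26, 45 and 3% of genes changed 1.5-fold. They found 70, 78, 69 and 43% of those changed 2-fold, so small changes were often missed in these simulations. Of 97, 106, 121 and 50 calls, 5.15, 1.89, 5.79 and 8% were false. In the PC3 data 5118 genes were called, which eases the adjusted threshold. In the ARCaP data, co-culture library 2 did not share the change. These rates therefore do not carry over to the real comparison of either line. Among 200 lists of 20 genes drawn at random without regard to correlation, camera passed 1, 4, 2 and 3.50% of unchanged lists at an unadjusted p under 0.05, and 100, 100, 100 and 98.5% of lists with 10 raised members. Values that stood apart within a group of 4 libraries were found by Dixon's ratio (critical value 0.829).

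Computations used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.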

Results

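QuantSeq 3′ messenger RNA libraries, which read the 3′ ends of polyadenylated transcripts, were made from 2 human prostate cancer cell lines grown alone or with fat cells. PC3 is a line from a bone metastasis, and ARCaP(M) (here ARCaP) is given in the labels as derived from ascites fluid. Each line was cultured alone or for 48 to 72 h above adipocytes in Transwell inserts with 0.2 µm pores, which pass soluble factors and hold the cells apart. The adipocytes had been differentiated in collagen I for 8 to 10 days to at least 70% fat cells. The labels give 4 biological replicates for each of the 4 groups, and the p-values of single genes rest on the spread among them. Total counts per library averaged 15885109.8 ± 1746734 for PC3 alone, 12552912 ± 1944038 for PC3 in co-culture, 14167151 ± 1993695 for ARCaP alone and 12857038 ± 2174149 for ARCaP in co-culture (SD, n = 4 each). The shallowest library, PC3 co-culture 4, held 9728687 counts and the deepest, PC3 alone 3, held 17808227. Between 13889 and 14901 genes had a count in each library. A gene at 0 counts could lie at up to 0.169 to 0.309 counts-per-million (CPM), the level of 3 counts, which covers counting error only. Levels are given as scaled CPM (mean ± SD, n = 4 libraries per group) and changes as log2 fold changes of co-culture over alone (± SE, 4 against 4 libraries).

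In PC3, the first principal component (55.2% of the variance) separated the co-culture libraries from the alone libraries, and the second (15.4%) set co-culture library 4 (62.3) apart from co-culture libraries 1 to 3 (-29.6 to -19.4). In ARCaP, co-culture library 2 lay at -22.8 on the first component (36.4%), inside the range of the alone libraries (-26.0 to -21.2), while co-culture libraries 1, 3 and 4 lay between 37.1 and 42.2. Both of these libraries stayed in the comparisons, and the counts of genes without them are given as well.

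**Figure D1:**
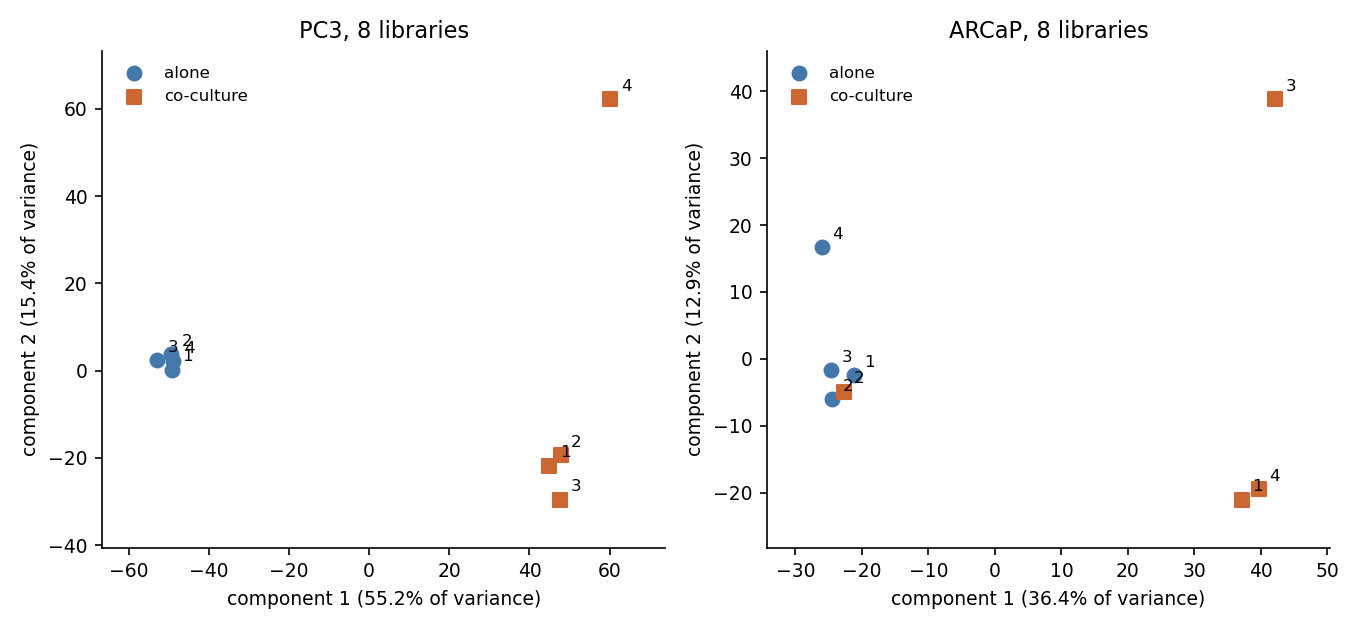
Principal components 1 and 2 of log2 CPM (unitless scores) for the 8 libraries of each line. Circles are alone libraries, squares are co-culture libraries, and the number beside each point is the replicate; ARCaP co-culture library 2 lies among the alone libraries and PC3 co-culture library 4 lies apart on component 2.

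The first comparison asked how PC3 cells differed after co-culture with adipocytes. Genes of the unfolded protein response rose, and genes of DNA replication and mitosis fell. HSPA5, which encodes the main chaperone of the endoplasmic reticulum (ER) lumen, went from 111 ± 7.87 to 1653 ± 102 CPM, a log2 fold change of 3.89 ± 0.09. DDIT3, which encodes the stress transcription factor CHOP, rose from 10.5 ± 3.09 to 205 ± 26.5 CPM (4.29 ± 0.18). Of 29 tested targets of the PERK/ATF4 branch, 28 rose, and all 22 tested genes of mitosis fell.

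By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2544 of 12761 tested genes were higher and 2574 lower at an adjusted p under 0.05, of which 946 and 913 changed by at least 2-fold. In 38.5% of tested genes the co-culture libraries all lay on one side of the alone libraries, against 2.86% by chance. In the authors' deposited table, 2159 genes were higher and 2727 lower in PC3 co-culture at an FDR under 0.05.

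Among genes with at least 10 CPM on average and no overlap between the groups, the 10 largest rises in PC3 began with CDH15, a cadherin (6.13 ± 0.27, 1.27 ± 0.717 to 91.5 ± 20.4 CPM), the kinase gene STK32A (5.72 ± 0.22), the signalling ligand SHH (5.39 ± 0.28), ANXA10 (5.31 ± 0.22) and S100P (5.13 ± 0.22). Next came the peptide hormone gene ADM2 (4.86 ± 0.41), the laminin chain LAMA4 (4.48 ± 0.30), TFF2, a secreted trefoil peptide (4.45 ± 0.21), TRIB3 (4.29 ± 0.11) and DDIT3. The 10 largest falls began with FAM111B (-6.17 ± 0.23, 67.2 ± 5.77 to 0.931 ± 0.376 CPM), the bombesin-family receptor GRPR (-4.29 ± 0.20), GINS2 (-3.81 ± 0.22), MCM10 (-3.72 ± 0.23), DTL (-3.68 ± 0.14) and CLSPN (-3.61 ± 0.18). They went on with ZNF704 (-3.53 ± 0.16), CDCA7 (-3.43 ± 0.31), the noncoding RNA LINC00261 (-3.39 ± 0.13) and WDR76 (-3.35 ± 0.23). GINS2, MCM10, DTL and CLSPN act in DNA replication and its checkpoint. The largest adjusted p among these 20 genes was 2.50e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the GRCh38 annotation CDH15 lies on chromosome 16, 89171767 to 89195492, STK32A on chromosome 5, 147234963 to 147387852, FAM111B on chromosome 11, 59107185 to 59127410 and GRPR on chromosome X, 16123556 to 16153021. DDIT3 overlaps MARS and MBD6 and GINS2 overlaps GSE1, each on the opposite strand, and whether counting used strand is not given in the sources used here. DDIT3 also overlaps the protein-coding entry AC022506.1 on the same strand.

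Of the 6 genes fixed for both lines, all 6 rose in PC3. HSPA5 (chromosome 9, 125234853 to 125241330), XBP1 (chromosome 22, 28794555 to 28800597), ATF4 (chromosome 22, 39519695 to 39522685) and DDIT3 (chromosome 12, 57516588 to 57521737) belong to the unfolded protein response and its integrated stress arm. XBP1 went from 50.7 ± 3.98 to 159 ± 18.3 CPM (1.65 ± 0.11) and ATF4 from 41.9 ± 5.80 to 320.4 ± 56.7 CPM (2.93 ± 0.13). HMOX1 (chromosome 22, 35380361 to 35394214), which encodes haem oxygenase 1, went from 3.17 ± 1.74 to 30.8 ± 8.20 CPM (3.26 ± 0.31). PLIN2 (chromosome 9, 19108375 to 19149290), which encodes a lipid droplet coat protein, went from 71.0 ± 7.88 to 713 ± 95.8 CPM (3.33 ± 0.12). The largest adjusted p of the 6 was 3.70e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

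**Figure D2:**
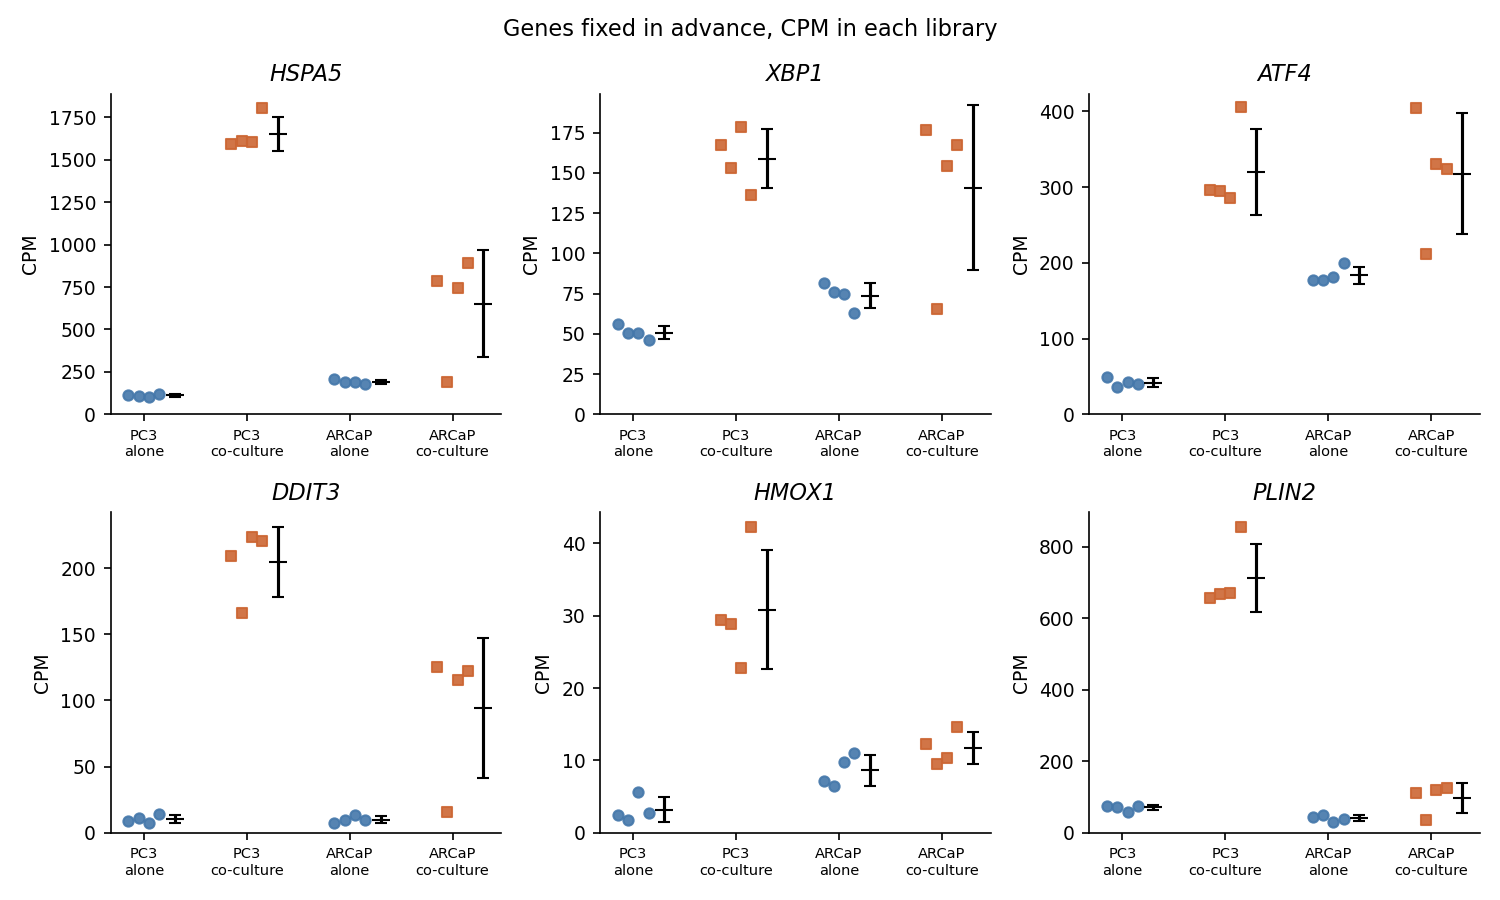
Scaled CPM (y axis) of the 6 genes fixed in advance in each of the 16 libraries, by line and condition, with the mean and SD of each group (n = 4) at the right of its points. HSPA5 reached 1653 CPM on average in PC3 co-culture and 652 CPM in ARCaP co-culture, where library 2 sits at the level of the alone libraries.

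Of 26 tested ER chaperones and targets of ATF6 and XBP1, 25 rose in PC3 and none fell, and 25 rose when adjusted over the list alone (median log2 fold change 2.04, camera adjusted p = 9.71e-19). Examples are the co-chaperones DNAJC3 (2.73 ± 0.09) and DNAJB11 (2.54 ± 0.09). Of the PERK/ATF4 targets 28 of 29 rose, 28 when adjusted over the list alone (median 2.44, camera adjusted p = 2.66e-20). Among them were the stress cytokine GDF15 (2.82 ± 0.08), DDIT4, an inhibitor of mTORC1 (3.20 ± 0.12), and the amino acid transporter subunit SLC3A2 (2.53 ± 0.10). Co-culture library 4 had an ER list level of 1.93 log2 units above the alone mean, against 2.22 to 2.26 in libraries 1 to 3.

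Of 20 tested genes of DNA replication and S phase, 18 fell and 19 fell when adjusted over the list alone (median -2.08, camera adjusted p = 3.78e-14). Examples are the ribonucleotide reductase subunit RRM2 (-3.16 ± 0.10) and the flap endonuclease FEN1 (-2.28 ± 0.10). The 22 mitotic genes, all lower also when adjusted over the list alone, had a median of -1.32 (camera adjusted p = 3.78e-14), with CDK1 at -1.68 ± 0.10 and AURKB at -1.88 ± 0.12. These 4 lists also passed with an estimated correlation among their genes (largest adjusted p = 0.00301). Of 15 cytosolic heat shock genes, 12 fell and none rose (12 and 1 when adjusted over the list alone, median -0.82, camera adjusted p = 2.04e-04, adjusted p = 0.0755 with an estimated correlation), such as HSP90AA1 (-1.31 ± 0.09) and HSPE1 (-1.17 ± 0.14).

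**Figure D3:**
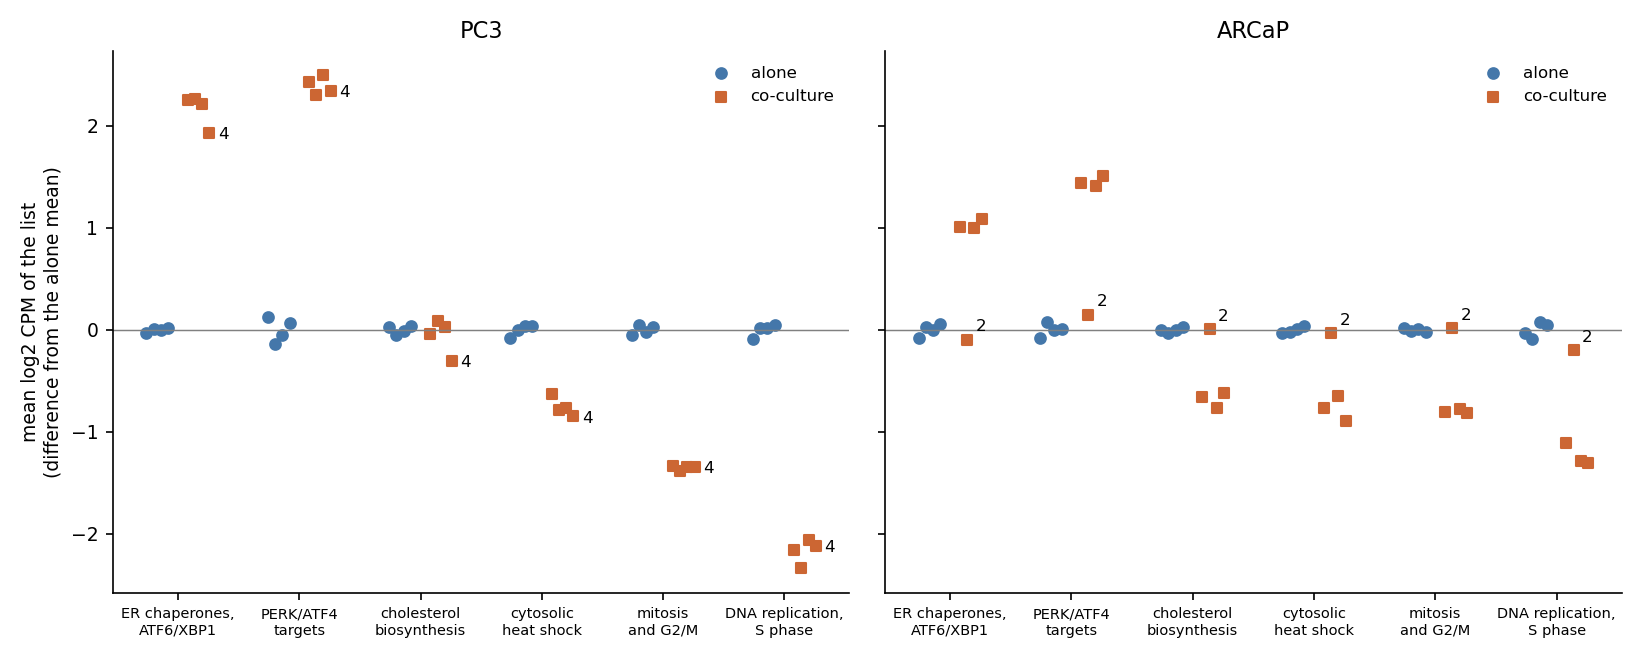
Mean log2 CPM of 6 gene lists in each library, as the difference from the mean of the alone libraries of the same line (log2 units). In PC3 all 4 co-culture libraries lie apart from the alone libraries for both unfolded protein response lists, while in ARCaP co-culture library 2 (marked) lies with the alone libraries at 0.15 for the PERK/ATF4 targets.

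Of 20 genes of lipid droplets, lipid uptake and fatty acid oxidation, 9 rose and 2 fell in PC3, with equal counts when adjusted over the list alone (camera adjusted p = 0.0170, adjusted p = 0.0755 with an estimated correlation). Besides PLIN2 these included ANGPTL4 (3.95 ± 0.25), an inhibitor of lipoprotein lipase, and PDK4 (2.55 ± 0.19), which restrains pyruvate oxidation. In co-culture library 4 this list lay 0.21 log2 units above the alone mean, against 0.63 to 0.71 in libraries 1 to 3. Of 14 p53 targets 6 rose and 1 fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.0330, adjusted p = 0.116 with an estimated correlation), with the cell cycle inhibitor CDKN1A at 2.63 ± 0.17. Of 17 genes of lysosomes and autophagy 8 rose and 1 fell, or 8 and 2 when adjusted over the list alone (camera adjusted p = 0.0330, adjusted p = 0.116 with an estimated correlation), among them WIPI1 (2.54 ± 0.12) and SQSTM1 (1.36 ± 0.09). The p53 list lost its call without co-culture library 4 (camera adjusted p = 0.0634) and the lysosome list without co-culture library 1 (camera adjusted p = 0.0728) or with the replicate number as a block (0.0749).

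Leaving aside the markers of other cell types, given further below, the other lists did not pass camera in PC3. With fry, fatty acid synthesis (adjusted p = 1.79e-05), NRF2 (3.06e-04), hypoxia (6.85e-04), metallothioneins (0.00434) and epithelial-mesenchymal transition (0.0193) did pass. This test asks whether the members shifted together in one direction, and does not compare them with other genes. With 2544 of 12761 genes higher and 2574 lower in PC3, many genes changed. Passing fry therefore does not show that a list stood out from other genes. Cholesterol biosynthesis had 4 genes higher and 8 lower of 22 (camera adjusted p = 0.675), with the sterol carrier STARD4 at 1.64 ± 0.16 and DHCR7 at -0.71 ± 0.11. Its median (-0.037) and mean (0.0071) differed in sign. Fatty acid synthesis had 0 higher and 4 lower of 12 (camera adjusted p = 0.169), with the fatty acid synthase gene FASN at -1.10 ± 0.13. Glycolysis had 3 higher and 6 lower of 19 (camera adjusted p = 0.491), with the glucose transporter SLC2A1 at 1.83 ± 0.11. Hypoxia response genes were higher in 7 and lower in 1 of 15 cases (camera adjusted p = 0.0837), VEGFA standing at 2.10 ± 0.17 and CA12 at -1.69 ± 0.17, and without co-culture library 4 the list passed (camera adjusted p = 0.0432). Among NRF2 and oxidative stress genes 5 rose and 2 fell of 16 (camera adjusted p = 0.151), with AKR1C1 at 4.38 ± 0.31 and TXNRD1 at -0.70 ± 0.09. Among epithelial-mesenchymal transition and matrix genes 9 rose and 5 fell of 22 (camera adjusted p = 0.353), E-cadherin (CDH1) being at 3.30 ± 0.17 and the matricellular gene CTGF at -3.18 ± 0.17. This list holds epithelial genes such as CDH1 and EPCAM beside mesenchymal ones such as VIM. Its direction is therefore not that of the transition, in either line. Glucocorticoid receptor targets had 4 higher and 2 lower of 9 (camera adjusted p = 0.414), with ERRFI1 at 2.40 ± 0.12 and FKBP5 at -2.91 ± 0.32. Interferon response genes had 4 higher and 5 lower of 19 (camera adjusted p = 0.913, OAS1 2.48 ± 0.18) and NF-kB targets and chemokines 2 and 2 of 15 (camera adjusted p = 0.685). Metallothioneins and zinc transport had 0 higher and 2 lower of 5 (camera adjusted p = 0.677, MT2A -0.76 ± 0.08), and oxidative phosphorylation 5 and 3 of 21 (camera adjusted p = 0.687). The median and the mean differed in sign for the metallothioneins (0.26 and -0.17) and for oxidative phosphorylation (0.046 and -0.014). When adjusted over the list alone, the counts higher and lower stayed as given for these lists except glycolysis (3 and 7), NF-kB (2 and 1) and oxidative phosphorylation (5 and 2).

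Markers of the other cell types of the co-culture were also measured in PC3. The labels do not give the species of the adipocytes, and RNA of a species other than human would not be fully counted under these symbols. Of 15 adipocyte markers 7 were expressed enough to be tested, 4 of them higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.414, fry adjusted p = 9.22e-04). The fatty acid carrier FABP4 went from 45.0 ± 7.35 to 198 ± 36.5 CPM (2.14 ± 0.15) and the droplet protein PLIN4 from 3.67 ± 1.27 to 20.3 ± 1.08 CPM (2.46 ± 0.23). PPARG, the master regulator of fat cell differentiation, went from 239 ± 18.2 to 122 ± 23.5 CPM (-0.97 ± 0.13). ADIPOQ, which encodes the abundant fat cell hormone adiponectin, and LEP, which encodes leptin, had 0 counts in all 16 libraries. Of 6 tested stromal and fibroblast markers 5 fell, also when adjusted over the list alone (camera adjusted p = 0.00957, adjusted p = 0.0755 with an estimated correlation), among them COL1A1 (-0.97 ± 0.15) and SPARC (-2.04 ± 0.49). This list lost its call without alone library 1 (camera adjusted p = 0.0610), alone library 4 (0.0551) or co-culture library 4 (0.0838), and with no filter on low counts (0.0523). CD68, the 1 haematopoietic marker tested, stood at 1.86 ± 0.37. The 2 entries read by their synonyms as mitochondrial ribosomal RNAs, tested as a sign of RNA quality, RNR1 (0.55 ± 0.15) and RNR2 (0.42 ± 0.10), were higher in co-culture. With total-count scaling both lost the call (adjusted p = 0.0641 and 0.0862 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

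Scaling by library totals alone, without the composition factors of the trimmed mean of M-values, shifted the median PC3 fold change by -0.20 log2 units and gave 1703 genes higher and 3969 lower (30.0% higher, against 49.7%), so changes are relative to this shift. Without co-culture library 4, 2888 genes were higher and 2883 lower of 13022 tested, and 4925 of the calls were kept in their direction.

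The second comparison asked the same of ARCaP cells. Many genes of the unfolded protein response were again higher, and some genes of the cell cycle were lower. DDIT3 went from 9.98 ± 2.39 to 94.5 ± 52.9 CPM (3.24 ± 0.45), and HSPA5 from 191 ± 10.3 to 652 ± 315 CPM (1.77 ± 0.31). Of 27 tested PERK/ATF4 targets 23 rose, and of 21 genes of DNA replication 6 and of 22 of mitosis 9 fell. Both unfolded protein response lists and both cell cycle lists passed camera with its preset correlation, but not with an estimated correlation (adjusted p from 0.307 to 0.327) or with fry (0.0690 to 0.0705). In co-culture library 2 the PERK/ATF4 list lay 0.15 log2 units above the alone mean, against 1.41 to 1.51 in libraries 1, 3 and 4.

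By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 389 of 12496 tested genes were higher and 228 lower at an adjusted p under 0.05. Of these, 104 and 10 changed by at least 2-fold. In 9.46% of genes the groups did not overlap, against 2.86% by chance if all libraries are alike. Co-culture library 2 lay with the alone libraries, while the other co-culture libraries differed from them. Genes changed only in those others can show no overlap through the chance position of library 2. The excess over 2.86% therefore does not show a change shared by every co-culture library. Without co-culture library 2, 1784 genes were higher and 1901 lower of 12717, and all 617 calls were kept in their direction. Leaving out each library in turn was planned, but this one was singled out after its position had been seen, so these larger counts are not independent evidence. Leaving out any other single library gave 0 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 2262 to 2657 genes at an unadjusted p under 0.05, where DESeq2 called 237 to 404 higher and 143 to 281 lower. In the authors' deposited table, 658 genes were higher and 502 lower in ARCaP co-culture at an FDR under 0.05.

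The 10 largest rises in ARCaP, again among genes with at least 10 CPM and no overlap between the groups, began with DDIT3, ADM2 (3.02 ± 0.40), GDF15 (2.72 ± 0.41), the stress transcription factor ATF3 (2.06 ± 0.33) and the ER-phagy receptor CCPG1 (1.94 ± 0.31). Next came the cystine transporter SLC7A11 (1.84 ± 0.29), the histone demethylase KDM7A (1.84 ± 0.33), SEL1L of the ER-associated degradation machinery (1.55 ± 0.22), TRIB3 (1.49 ± 0.24) and the pro-apoptotic gene BBC3 (1.45 ± 0.22). The condition of no overlap left out SESN2, HERPUD1 and CHAC1, given further below, which passed the threshold and rose more than ATF3. Which genes meet this condition depends on co-culture library 2, which lay with the alone libraries. The 10 largest falls were those of FAM111B (-1.68 ± 0.41), the phosphatase CDC25A (-1.13 ± 0.31), CLSPN (-1.12 ± 0.27), GINS2 (-1.12 ± 0.24), SUV39H1 (-1.08 ± 0.22), ATAD5 (-0.98 ± 0.21), WDR62 (-0.94 ± 0.22), HELLS (-0.93 ± 0.20), TOE1 (-0.92 ± 0.24) and MCM5 (-0.90 ± 0.17). The largest adjusted p among these 20 was 0.0466 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without co-culture library 2 all 20 changes were larger in size, with DDIT3 at 3.60, ADM2 at 3.33, FAM111B at -2.63, CDC25A at -1.67 and CLSPN at -1.66. That library lay with the alone libraries, so leaving it out enlarges such changes by construction and adds no evidence for them. CCPG1 shares its strand with an annotated readthrough transcript with DNAAF4, HELLS overlaps TBC1D12 on the same strand and SLC7A11 overlaps SLC7A11-AS1 on the other, so reads of these genes can be split or shared. Of the fixed genes, XBP1 went from 73.7 ± 7.94 to 141 ± 51.2 CPM (0.93 ± 0.22), ATF4 from 184 ± 11.1 to 318 ± 80.0 CPM (0.79 ± 0.15) and PLIN2 from 41.0 ± 8.59 to 97.7 ± 42.2 CPM (1.25 ± 0.28). The largest adjusted p of the 5 that passed was 0.0338 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. HMOX1 did not pass, at 8.63 ± 2.13 to 11.7 ± 2.25 CPM (0.44 ± 0.23, adjusted p = 0.257 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

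Of 26 tested ER chaperones and ATF6/XBP1 targets 17 rose in ARCaP and none fell, 20 when adjusted over the list alone (median 0.77, camera adjusted p = 7.62e-08, adjusted p = 0.327 with an estimated correlation). Among them were HERPUD1 (2.56 ± 0.41), which acts in ER-associated degradation, and the co-chaperone DNAJB9 (1.71 ± 0.31). Of the PERK/ATF4 targets 23 of 27 rose, 26 when adjusted over the list alone (median 0.80, camera adjusted p = 1.55e-13, adjusted p = 0.307 with an estimated correlation), among them SESN2 (2.79 ± 0.43) and CHAC1 (2.55 ± 0.44). Without co-culture library 2 both passed with an estimated correlation, at 22 of 26 (adjusted p = 0.0130) and 26 of 27 (adjusted p = 0.00513).

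Genes of the cell cycle fell in ARCaP, with 6 of 21 replication genes (17 when adjusted over the list alone, median -0.82, camera adjusted p = 1.54e-10, adjusted p = 0.307 with an estimated correlation). The same held for 9 of 22 mitotic genes (19 when adjusted over the list alone, median -0.56, camera adjusted p = 7.69e-10, adjusted p = 0.307 with an estimated correlation). The helicase subunit MCM7 stood at -0.78 ± 0.17 and the checkpoint kinase BUB1B at -0.86 ± 0.20. Without co-culture library 2, 19 replication and 22 mitotic genes fell (adjusted p = 0.00513 for each list with an estimated correlation). Of 15 cytosolic heat shock genes 6 fell, 12 when adjusted over the list alone (median -0.50, camera adjusted p = 9.40e-08, adjusted p = 0.307 with an estimated correlation), with HSP90AA1 at -0.84 ± 0.18.

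Cholesterol biosynthesis fell as a list in ARCaP (median -0.55, camera adjusted p = 4.62e-06, adjusted p = 0.307 with an estimated correlation), with 2 genes lower and 1 higher of 21, or 12 and 1 when adjusted over the list alone. The sterol enzymes EBP (-0.80 ± 0.21) and MSMO1 (-0.73 ± 0.20) were the members that fell, and STARD4 (0.76 ± 0.14) the member that rose. Without co-culture library 2, 16 fell and 2 rose (adjusted p = 0.00693 with an estimated correlation). Fatty acid synthesis had 1 gene lower of 11 (4 when adjusted over the list alone, camera adjusted p = 0.0161, adjusted p = 0.343 with an estimated correlation), the desaturase FADS1 (-0.56 ± 0.14). Hypoxia response genes rose in 3 of 14 cases (7 when adjusted over the list alone, camera adjusted p = 0.00451, adjusted p = 0.307 with an estimated correlation), VEGFA being at 0.91 ± 0.19. Of 10 glucocorticoid receptor targets 3 rose and 1 fell, or 4 and 1 when adjusted over the list alone (camera adjusted p = 0.0470, adjusted p = 0.343 with an estimated correlation). TSC22D3 stood at 1.11 ± 0.25 and FKBP5, whose call was lost with total-count scaling (adjusted p = 0.0502 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), at -0.48 ± 0.13. This list lost its call when any library but alone 4 and co-culture 2 was left out (camera adjusted p from 0.0517 to 0.114) and with the replicate number as a block (0.0745), and oxidative phosphorylation lost it without co-culture library 3 (camera adjusted p = 0.0543). Of 21 oxidative phosphorylation genes 3 fell, also when adjusted over the list alone (camera adjusted p = 0.0198, adjusted p = 0.307 with an estimated correlation), with SDHA at -0.61 ± 0.14.

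The remaining lists did not pass in ARCaP. They were lipid droplets, uptake and oxidation (3 higher and 0 lower of 18, camera adjusted p = 0.411, CPT1A 0.53 ± 0.12), epithelial-mesenchymal transition and matrix (3 and 1 of 21, camera adjusted p = 0.0600) and lysosome and autophagy (1 and 1 of 18, camera adjusted p = 0.0676). They were also p53 targets (1 and 0 of 15, camera adjusted p = 0.394), glycolysis (1 and 2 of 20, camera adjusted p = 0.872), NRF2 (0 and 1 of 14, camera adjusted p = 0.804), NF-kB (1 and 0 of 11, camera adjusted p = 0.116), interferon response (0 and 0 of 18, camera adjusted p = 0.144) and metallothioneins (0 and 0 of 6, camera adjusted p = 0.380). When adjusted over the list alone, the counts higher and lower were 4 and 0 for lipid droplets, 6 and 2 for epithelial-mesenchymal transition, 5 and 1 for lysosomes, 3 and 2 for p53, 3 and 3 for glycolysis, 1 and 1 for NRF2 and 1 and 3 for NF-kB. With co-culture library 2 left out the lists of epithelial-mesenchymal transition (camera adjusted p = 0.0286), lysosomes (0.0154) and NF-kB targets (0.0314) passed. Of all lists that then passed, 6 were higher and 7 lower, and these added lists did not all go in one direction. Median and mean differed in sign for metallothioneins (-0.15 and 0.016). Of the 4 adipocyte, 4 stromal and 5 haematopoietic markers tested, and of RNR1 and RNR2, none passed at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Adjusted over the list alone, 2 adipocyte markers were higher. The set test of the haematopoietic list did not pass (camera adjusted p = 0.144).

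**Figure D4:**
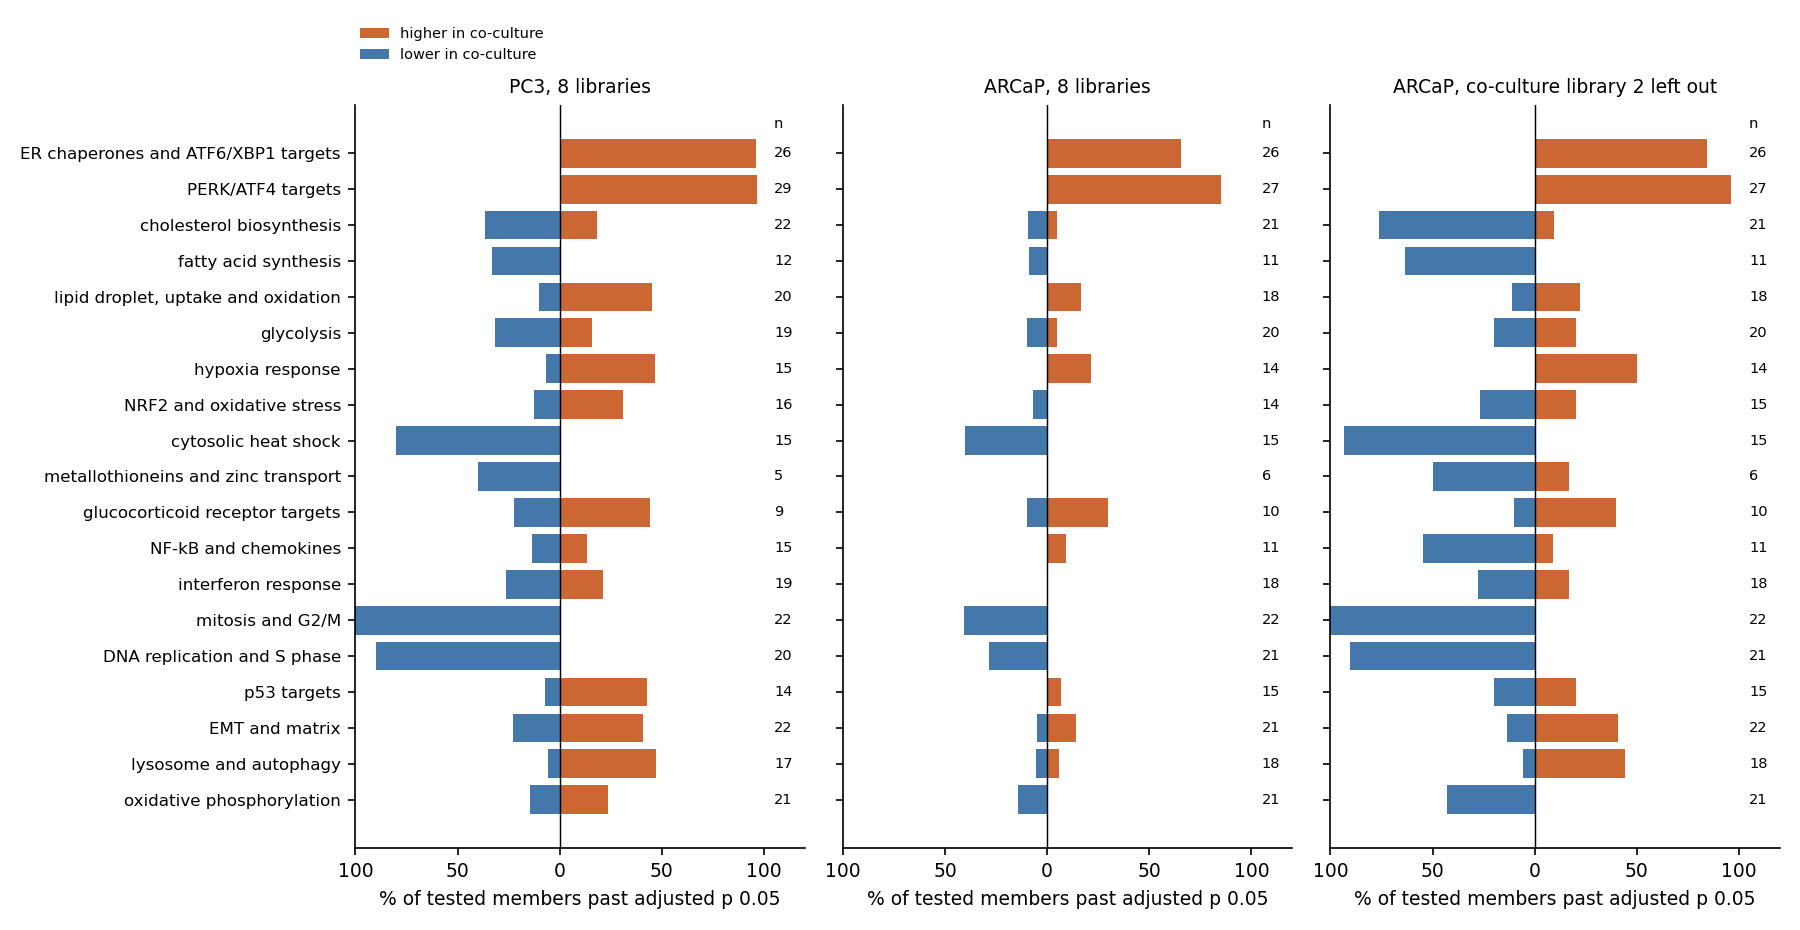
Share of tested members of each list (x axis, %) that were higher (right) or lower (left) in co-culture at an adjusted p under 0.05, with the number tested (n) at the right, for PC3, for ARCaP, and for ARCaP without co-culture library 2, which was singled out after it had been seen. The PERK/ATF4 list has 28 of 29 members higher in PC3, 23 of 27 in ARCaP and 26 of 27 in the right panel.

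The series title speaks of a signature shared by both lines, and the third comparison asked which genes changed in the same direction in each. Among the 11378 genes tested in both, 233 rose in both lines, against 72.5 expected of independent lists (one-sided Fisher exact test with genes as its units, p = 4.07e-78), and 158 fell in both, against 46.3 (p = 4.00e-59). The 10 shared genes with at least 10 CPM on average in each line whose weaker change was largest, all higher, were DDIT3, ADM2, SESN2, GDF15, HERPUD1, CHAC1, SLC7A11, STC2, SLFN5 and HSPA5. In PC3 SESN2 stood at 4.14 ± 0.18, HERPUD1 at 3.69 ± 0.22, CHAC1, which degrades glutathione, at 4.17 ± 0.19, SLC7A11 at 2.27 ± 0.14, STC2 at 2.05 ± 0.10 and SLFN5 at 1.82 ± 0.10. In ARCaP STC2 stood at 1.83 ± 0.36 and SLFN5 at 2.06 ± 0.38. In opposite directions, 7 genes were higher in PC3 and lower in ARCaP and 21 lower in PC3 and higher in ARCaP. Across the 11378 genes, which are not independent replicates, the log2 fold changes of both lines had a Pearson r of 0.391 and a Spearman rho of 0.384, and 498 of the 587 genes called in ARCaP (84.8%) had the same sign in PC3. Without ARCaP co-culture library 2, 799 genes rose in both lines (expected 333) and 1000 fell in both (expected 375). Leaving out any other ARCaP library ended the ARCaP calls by edgeR and with them the overlap.

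**Figure D5:**
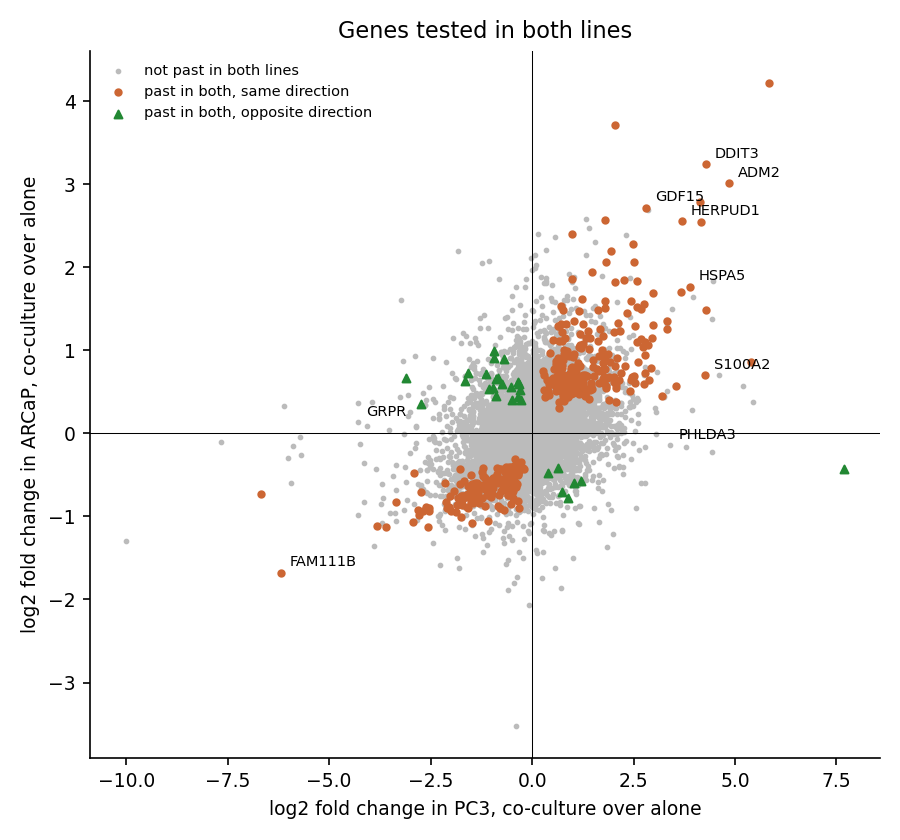
Log2 fold change of co-culture over alone in PC3 (x axis) and ARCaP (y axis) for the 11378 genes tested in both lines. Coloured points passed an adjusted p under 0.05 in both lines, 233 higher in both and 158 lower in both in circles, and 7 and 21 in opposite directions in triangles.

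The fourth comparison tested whether the change in PC3 differed from that in ARCaP. Many stress genes, though not all, rose further in PC3, and many cell cycle genes fell further. HSPA5 rose by 2.09 ± 0.37 log2 units more in PC3 than in ARCaP, ATF4 by 2.11 ± 0.22, HMOX1 by 2.79 ± 0.41 and PLIN2 by 2.05 ± 0.35. ATF4 reached similar CPM in co-culture of both lines, starting from a lower level in PC3 alone. CPM were scaled within each line separately, so levels compare only roughly between the lines. These differences include the ARCaP co-culture library that lay with the alone libraries. ER chaperones and ATF6/XBP1 targets differed by a median of 1.21 log2 units and replication genes by -1.30, but neither list passed with an estimated correlation (adjusted p = 0.276 for both). The differences of GDF15, STC2, SLC7A11 and DDIT3 did not pass.

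By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment on the difference of the changes, 995 of 14094 genes had a difference (PC3 minus ARCaP) above 0 and 1231 below 0. Among the 10 with the smallest p were PHLDA3 (3.52 ± 0.14, chromosome 1, 201464383 to 201469237), GRPR (-4.46 ± 0.23), the calcium-binding protein gene S100A2 (3.54 ± 0.20, chromosome 1, 153561108 to 153567890), and DDIT4 (2.71 ± 0.16). Also among them were DNAJC10, an ER disulfide reductase (1.99 ± 0.12), SEMA4B (2.15 ± 0.14), PAG1 (-3.80 ± 0.25), TMEM158 (1.93 ± 0.13) and the kinase gene PLK2 (-3.12 ± 0.21). Their largest adjusted p was 1.38e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. S100A2 went from 308 ± 35.4 to 5932 ± 566 CPM in PC3 and from 185 ± 15.9 to 299.5 ± 76.0 CPM in ARCaP. PAG1 went from 32.0 ± 3.08 to 3.75 ± 0.891 CPM in PC3 and from 16.8 ± 1.38 to 26.6 ± 4.54 CPM in ARCaP. PLK2 went from 61.5 ± 5.64 to 9.11 ± 3.13 CPM and from 611 ± 24.2 to 780.1 ± 96.6 CPM. PHLDA3 rose in PC3 (3.41 ± 0.12) and stood at -0.14 ± 0.09 in ARCaP (adjusted p = 0.328 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the shared genes, CHAC1 differed as well (1.60 ± 0.54, adjusted p = 0.0494 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). That call was lost with total-count scaling (adjusted p = 0.0722), with DESeq2 (0.0864) and when any 1 of 12 libraries was left out (up to 0.130). It was kept without ARCaP co-culture library 2. The differences of DDIT3 (1.02 ± 0.54, adjusted p = 0.224), ADM2 (adjusted p = 0.0558), SESN2 (0.0950), HERPUD1 (0.165), SLC7A11 (0.520), STC2 (0.840), GDF15 (0.994), SLFN5 (0.759) and XBP1 (0.103) did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That of ADM2 did pass with DESeq2 (0.0204), with no filter (0.0243), with a minimum of 10 CPM (0.0474) and with the replicate number as a block (0.0174). It also passed without PC3 alone 4 (0.0113) or PC3 co-culture 1 (0.0454), and that of SESN2 with no filter (0.0324). By the same test without ARCaP co-culture library 2, the differences of SESN2 (0.96, adjusted p = 0.00303), ADM2 (1.50, 0.0438) and XBP1 (0.44, 0.0446) passed above 0 and that of SLFN5 (-0.62, 0.0107) below 0.

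Among lists, the set test on the difference, added after the results per line had been seen, passed for ER chaperones (19 of 27 genes above 0 and none below, camera adjusted p = 2.26e-13, adjusted p = 0.276 with an estimated correlation), PERK/ATF4 targets (15 of 29, median 1.02, camera adjusted p = 1.75e-12, adjusted p = 0.276 with an estimated correlation) and replication (16 of 21 below 0, camera adjusted p = 4.21e-07, adjusted p = 0.276 with an estimated correlation). It also passed for mitosis (14 of 22 below 0, median -0.79, camera adjusted p = 2.51e-07, adjusted p = 0.303 with an estimated correlation) and cholesterol biosynthesis (3 of 23 above 0, median 0.38, camera adjusted p = 0.00764, adjusted p = 0.402 with an estimated correlation), and for p53 targets (3 of 15 above 0, median 0.44, camera adjusted p = 0.0106, adjusted p = 0.276 with an estimated correlation) and lipid droplets (4 of 20 above 0, median 0.11, camera adjusted p = 0.0454, adjusted p = 0.276 with an estimated correlation). When adjusted over the list alone the counts were 22, 18, 17, 20, 3, 6 and 5 in the same order. The lipid droplet list lost its call with the replicate number as a block (camera adjusted p = 0.0548) and with total-count scaling (0.0587). The other lists did not pass, the smallest camera adjusted p being 0.0761 for the NRF2 list. Without ARCaP co-culture library 2, 1178 genes had a difference above 0 and 1388 below. With an estimated correlation the lists then passed at adjusted p = 8.51e-04 for ER chaperones, 7.56e-04 for PERK/ATF4 targets, 7.56e-04 for replication, 7.56e-04 for mitosis, 8.82e-04 for cholesterol biosynthesis and 0.0179 for p53 targets, and not for lipid droplets (0.0558). Total-count scaling shifted the median difference by -0.16 log2 units and gave 703 genes above 0 and 2069 below (25.4% above, against 44.7%).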

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

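The tests of ARCaP co-culture library 2, the response score of PC3 co-culture library 4 and all tests that use thinning, total-count scaling or the data without ARCaP co-culture library 2 were chosen only after the data had been seen; the tests of GC content and length and the splits of all libraries were chosen before their results.

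ARCaP co-culture library 2 lay with the alone libraries, with a PERK/ATF4 list level of 0.15 (others 1.41 to 1.51) and a chi-square per gene of 9.38 to 10.6 against alone libraries and 38.5 to 46.7 against the other co-culture libraries. A swap with an alone library needs an alone library at the co-culture level, but the highest stood at 0.0727, and an alone library deposited under both names should give a chi-square under 2, but the lowest was 9.38, near the 10.1 to 13.2 among alone libraries. Its depth of 13777198 counts was 1.34 times that of co-culture library 3 (10265093) and also above that of library 1 (12077619), and their list levels were 1.41 and 1.44, which argues against low depth. A candidate explanation is an ARCaP culture without exposure to adipocytes under a co-culture label: on a scale from 0 (alone mean) to 1 (mean of the other co-culture libraries) it scored 0.174, and alone libraries held out in turn scored 0.147 to 0.182. This is a hypothesis found and tested on the same data, and a culture that was exposed and did not respond stays open, as untested.

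PC3 co-culture library 4 stood apart from co-culture libraries 1 to 3, also with all 4 thinned to 9716841 counts, where its chi-square per gene was 28.2 to 36.2 against them and theirs among each other 6.84 to 11.1, which argues against low depth. Dilution with PC3 cells that had not responded should lower its response score, which was 0.908, while the others scored 0.856 to 0.884. Each of the others was scored against the mean of fewer libraries, which by itself lowers a score. The comparison is not like for like and does not decide on a slight dilution. Transcript length had a Spearman rho of -0.0166 across genes with its deviation from the others, inside the -0.148 to 0.164 of those libraries. GC content of the 3′ end had a rho of 0.268 (others -0.0583 to 0.0485), over 12315 of 12761 genes, which are not independent replicates. That value lies between the bounds set beforehand for and against GC content as the cause, so a GC-linked difference in library preparation and a difference between the cultures cannot be told apart.

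The ER chaperone and PERK/ATF4 lists rose more in PC3 than in ARCaP, by medians of 1.21 and 1.02 log2 units (camera adjusted p = 2.26e-13 and 1.75e-12, adjusted p = 0.276 for both with an estimated correlation). ARCaP co-culture library 2 is not the whole cause, since without it the medians were 0.99 and 0.87 and the larger camera adjusted p with an estimated correlation was 8.51e-04. With that library left out as well, total-count scaling gave medians of 0.83 and 0.71 (0.00107) and thinning to equal totals 0.97 and 0.92 (8.63e-04), which argues against scaling or total counts as the whole cause. A difference between the cell lines stays open, as does the growth medium, which went with the line, with 10% serum for PC3 and 5% for ARCaP, and neither was tested.

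By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1 of 35 splits of the PC3 libraries into groups of 4 gave as many as 5118 genes. This was the real split. A share of 1 in 35 is the smallest that so few splits can give, so it argues against chance without excluding it. The highest other split gave 0, with up to 1061 genes at an unadjusted p under 0.05 in other splits against 6074 in the real one. In ARCaP the real split, 1 of 35, gave 617 genes, and the 4 splits that exchange co-culture library 2 with an alone library gave 465 to 603. With so small a margin the share of splits does not exclude chance either. Without library 2 the real split, 1 of 35, gave 3685 genes and the highest other 2. Library 2 was left out because it did not lie with its group, which favours the real split. That result is therefore not a separate check on chance. For the difference between the lines, 3 of 100 drawn splits gave at least the real 2226 genes, the real one included. The other 2, with 2996 and 2877 genes, kept the real PC3 groups and regrouped the ARCaP libraries, as did a split with 2166, and no split that broke up the PC3 groups gave more than 26. The count follows the large PC3 change, a structure of the samples, so these splits do not decide whether chance gives the difference between the lines.

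Of 392 groups of 4 libraries tested over the named genes and lists, 43 held a library far from the other 3, where chance gives about 5%; 24 of them were in ARCaP co-culture, all in library 2, and 11 in PC3 co-culture, 10 of those in library 4. In ARCaP co-culture library 2 the list levels that stood apart (log2 units against the alone mean, with the range of the other 3) were ER chaperones (-0.10 against 1.00 to 1.09), PERK/ATF4 targets (0.15 against 1.41 to 1.51), fatty acid synthesis (0.058 against -0.53 to -0.44) and mitosis (0.016 against -0.82 to -0.78). Lower there (CPM, with the range of the other 3) were ADM2 (5.29 against 22.5 to 24.1), CHAC1 (11.7 against 73.7 to 84.7), CPT1A (66.4 against 87.6 to 91.8), DDIT3 (15.4 against 116 to 125), DNAJB9 (20.2 against 63.9 to 71.2), PLIN2 (35.0 against 111 to 125), STC2 (13.2 against 69.0 to 78.1) and TRIB3 (27.2 against 65.4 to 69.9). Higher there were ATAD5 (91.6 against 41.2 to 43.9), BUB1B (118 against 52.7 to 61.9), CLSPN (150.3 against 45.5 to 61.7), EBP (111 against 49.5 to 55.9), FADS1 (278 against 164 to 183), FAM111B (75.2 against 9.98 to 19.7), GINS2 (44.3 against 17.7 to 18.6), HELLS (217 against 97.0 to 109), HSP90AA1 (1039.6 against 514 to 560.2), MCM5 (66.4 against 37.6 to 40.2), MCM7 (567 against 293 to 307) and PHLDA3 (346 against 299 to 306). In PC3 co-culture library 4 the list levels that stood apart were ER chaperones (1.93 against 2.22 to 2.26), fatty acid synthesis (-0.31 against -0.29 to -0.28), lipid droplets (0.21 against 0.63 to 0.71) and hypoxia (0.082 against 0.34 to 0.39), and in library 2 that of the interferon response (0.093 against -0.063 to -0.055). Higher in PC3 co-culture library 4 were ATF4 (405 against 286 to 296), HSPA5 (1806 against 1592 to 1609) and PLIN2 (857 against 657 to 670.5), and lower ERRFI1 (536 against 744 to 776), PDK4 (41.7 against 62.3 to 64.5) and SLC7A11 (149.6 against 229.7 to 241). In the alone groups the values that stood apart (CPM) were those of CDH15 in PC3 alone library 3 (2.34 against 0.867 to 1.00), DNAJC10 in PC3 alone library 3 (171 against 152 to 154), SLC3A2 in PC3 alone library 1 (94.1 against 78.8 to 81.2), SLC7A11 in PC3 alone library 4 (49.3 against 42.2 to 42.6), HERPUD1 in ARCaP alone library 4 (79.8 against 49.8 to 53.5), RNR2 in ARCaP alone library 3 (14865 against 13147 to 13291), STARD4 in ARCaP alone library 2 (103 against 80.6 to 84.3) and SUV39H1 in ARCaP alone library 1 (26.4 against 21.5 to 22.2).

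The test of the difference of changes (PC3 minus ARCaP, log2 units) passed, among the genes, for PHLDA3 (3.52), GRPR (-4.46), S100A2 (3.54), DDIT4 (2.71), DNAJC10 (1.99), SEMA4B (2.15), PAG1 (-3.80), TMEM158 (1.93), PLK2 (-3.12), HSPA5 (2.09), ATF4 (2.11), HMOX1 (2.79), PLIN2 (2.05) and CHAC1 (1.60), the last lost in most alternatives that leave out 1 library (adjusted p up to 0.130 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It passed for the lists of ER chaperones (1.21), PERK/ATF4 targets (1.02), cholesterol biosynthesis (0.38), lipid droplets (0.11), mitosis (-0.79), DNA replication (-1.30) and p53 targets (0.44), given as medians, by camera with its preset correlation and by none of them with an estimated one.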

How the results depend on the processing

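Singling out ARCaP co-culture library 2 or PC3 co-culture library 4, total-count scaling and thinning to equal totals were chosen after seeing the data; the other alternatives, with each library left out in turn, were planned. Counts of genes are given as higher and lower, and the cause of a change was not tested unless the alternative's own construction (fewer libraries, a stricter threshold) gives it. In PC3 the counts stayed within 1.5 times 2544 and 2574 in the alternatives other than a minimum change of 1 log2 unit (946 and 913) and total-count scaling (3969 lower), and ran from 2237 to 2888 higher and 2232 to 2883 lower with 1 library left out. In ARCaP 389 and 228 became 719 and 608 with DESeq2, 643 and 618 with no filter, 420 lower with the replicate number as a block, 1784 and 1901 without co-culture library 2, 3 and 0 at a threshold of 0.01 and 104 and 10 with the minimum change. With 1 library left out they ran from 0 to 1784 higher and 0 to 1901 lower, at 0 by edgeR whenever a library other than co-culture 2 was missing (2262 to 2657 genes at an unadjusted p under 0.05, where DESeq2 called 237 to 404 higher and 143 to 281 lower), so by edgeR the ARCaP counts rest on each of those libraries. Genes whose change differed between the lines went from 995 above 0 and 1231 below to 2069 below with total-count scaling, 599 and 646 at the stricter threshold and 453 and 679 with the minimum change, and ran from 855 to 1178 and 968 to 1388 with 1 library left out. Genes shared by both lines became 376 higher and 375 lower with DESeq2, 413 lower with no filter, 301 lower with the block, 799 and 1000 without ARCaP library 2, 3 and 0 at the stricter threshold and 59 and 8 with the minimum change, and 0 to 799 and 0 to 1000 with 1 library left out. In PC3 the number of lists that passed was 2 higher and 2 lower with an estimated correlation, 9 higher with fry, and 4 to 5 and 3 to 4 with 1 library left out. In ARCaP it was 0 and 0 with an estimated correlation, 0 and 0 with fry, and 3 to 6 and 5 to 7 with 1 library left out. The adjusted p of the ER chaperone list ran over 5.84e-20 to 9.16e-18 in PC3 and 5.02e-14 to 1.0e-06 in ARCaP with 1 library left out, and was 0.327 and 0.0705 in ARCaP with an estimated correlation and with fry; that of the PERK/ATF4 list ran over 4.83e-21 to 6.72e-19 and 6.51e-20 to 2.84e-12, and was 0.307 and 0.0690. Of the named genes, 1 in PC3 lost its call with DESeq2 and 6 with total-count scaling, while in ARCaP 15 gained a call with DESeq2 and 35 without co-culture library 2, and 3 lost it with total-count scaling. Directions turned only in lists and genes that had not passed. These were the lists, with adjusted p, of the interferon response in PC3 (0.145 with fry, 0.949 with total-count scaling, 0.733 to 0.993 with 1 library left out, turned without PC3 alone 2 or PC3 co-culture 3), oxidative phosphorylation in PC3 (0.661 with total-count scaling), glycolysis in ARCaP (0.986 with no filter on low counts, 0.653 to 0.983 with 1 library left out, turned without ARCaP alone 3 or ARCaP co-culture 1) and NRF2 in ARCaP (0.729 to 0.995 with 1 library left out, turned without ARCaP alone 1, ARCaP alone 4, ARCaP co-culture 1 or ARCaP co-culture 3). They were also the log2 changes in ARCaP of RNR1 (-0.046 to 0.11 with 1 library left out, turned without ARCaP alone 4, ARCaP co-culture 3 or ARCaP co-culture 4), COL3A1 (-0.026 to 0.072 with 1 library left out, turned without ARCaP alone 3 or ARCaP co-culture 3) and SEMA4B (-0.0019 with no filter on low counts, -0.043 to 0.021 with 1 library left out, turned without ARCaP alone 3, ARCaP co-culture 1 or ARCaP co-culture 3), and the differences between the lines of GDF15 (-0.10 with total-count scaling, -0.29 to 0.25 with 1 library left out, turned without ARCaP co-culture 2) and STC2 (-0.14 to 0.39 with 1 library left out, turned without ARCaP co-culture 2). Lanes were not run alone because the tables hold them summed, and pseudocounts were not varied because the tables hold counts. Depending on the depth of the library, a gene at 0 counts could lie at up to 0.169 to 0.309 CPM, the level of 3 counts.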

Other observations

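The 6 lists described here were added after the main results; the tests of the hemidesmosome list were chosen only after some of its members had been seen, those of the other 5 lists before their values had been, and the genes given as examples were chosen after their values were seen.

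Besides the chaperones, genes of the secretory pathway and some aminoacyl-tRNA synthetases rose in PC3. Of 16 cytosolic aminoacyl-tRNA synthetases, which load tRNAs with amino acids, 11 rose and none fell (median 0.82, camera adjusted p = 4.15e-06, adjusted p = 0.0712 with an estimated correlation), with AARS at 2.39 ± 0.12 and GARS at 2.28 ± 0.11. Of 22 genes of the signal recognition particle and the translocon, which bring new proteins into the ER, 16 rose (camera adjusted p = 2.62e-06, adjusted p = 0.0278 with an estimated correlation), among them SSR3 (1.60 ± 0.09) and SEC11C (1.91 ± 0.12). Of 11 subunits of the oligosaccharyltransferase, which attaches glycans, 9 rose (camera adjusted p = 5.19e-05, adjusted p = 0.0843 with an estimated correlation and 0.0157 without co-culture library 4), with MAGT1 at 1.39 ± 0.09. Of 22 genes of the COPII and COPI coats of transport vesicles and their cargo receptors, 15 rose (camera adjusted p = 3.73e-06, adjusted p = 0.0254 with an estimated correlation), with LMAN1 at 1.16 ± 0.07.

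In ARCaP these lists did not pass, with 2 higher and 1 lower of 16 synthetases (camera adjusted p = 0.122), 0 and 0 of 22 translocon genes (camera adjusted p = 0.485), 1 and 0 of 10 oligosaccharyltransferase subunits (camera adjusted p = 0.184) and 2 and 0 of 22 coat genes (camera adjusted p = 0.151). With co-culture library 2 left out the synthetases passed with 9 higher and 1 lower (camera adjusted p = 0.0149, adjusted p = 0.0889 with an estimated correlation). The difference between the lines (PC3 minus ARCaP) passed for each of the 4 lists, with medians from 0.35 to 0.75 log2 units (camera adjusted p at most 2.06e-06, and at most 0.0235 with an estimated correlation). The hypothesis that the proteasome rose along with the ER lists was not borne out: of its 31 subunits 1 rose and 9 fell in PC3 (camera adjusted p = 0.0566), and 5 fell in ARCaP (camera adjusted p = 2.26e-07, adjusted p = 0.306 with an estimated correlation). Without co-culture library 2, 24 subunits fell in ARCaP (adjusted p = 0.00984 with an estimated correlation), and the difference between the lines, which had not passed (camera adjusted p = 0.117), did (camera adjusted p = 0.00547, adjusted p = 0.0762 with an estimated correlation).

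Genes of hemidesmosomes, which anchor epithelial cells to the basement membrane, and of basal epithelium were also higher in PC3 co-culture. Of 9 tested, 7 rose and none fell (median 1.63, camera adjusted p = 2.62e-06, adjusted p = 0.0115 with an estimated correlation), among them the laminin chain LAMB3 (3.43 ± 0.11) and the integrin subunit ITGB4 (2.77 ± 0.10). In ARCaP 5 of 9 rose and the list did not pass (camera adjusted p = 0.122). The difference between the lines passed (median 1.39, camera adjusted p = 3.74e-07, adjusted p = 7.89e-04 with an estimated correlation). The list was drawn up after S100A2 and 1 other gene that it holds had been seen to differ, so its tests are not independent evidence.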
